A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

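Total RNA came from smooth muscle cells of rabbit basilar arteries. Per the labels, the arteries were perfused with elastase and collagenase for 45 min on day 5 after ligation or exposure of both carotid arteries, and the cells were released by trituration. Per the labels, RNA was taken up with TRIzol, checked for integrity, cleaned with DNase treatment, and labelled with Cy3 by a low-input one-colour kit. Each of 6 arrays came with its own scanner output, 3 from sham and 3 from ligated rabbits. Per the labels, the scans were read with Agilent Feature Extraction 10.7. Per the file headers, the processed signal of each spot is an intensity after background subtraction and detrending within the array, with no scaling between arrays, and low values are replaced by a surrogate. The deposited raw spot signal and local background are also intensity values with no processing. The spot marks (well above background, saturated, non-uniform or population outlier) are, per the file headers, flags of the kind other, each 0 or 1. The deposited value table is in log2 units. Its columns had equal quantiles (array medians of 5.05) and correlated with the log2 processed signal at 0.999 or more, and the step that made it is not given in the sources used here.

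The analysis started from the processed signal. Spots marked as outliers were left out (7, 2 and 13 on the sham arrays, and 2, 19 and 16 on the ligated arrays), the repeated spots of a probe were averaged on the log2 scale (50 probes were spotted more than once), and the 75th percentile of each array was subtracted. That percentile was a signal of 222, 207 and 224 on the sham arrays, and 181, 251 and 157 on the ligated arrays. The slope of the spike-in controls ran from 1.01 to 1.03. A probe was tested when it was well above background on at least 3 of the 6 arrays, which kept 27410 of 43603 probes. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model with moderated variances, 4 residual degrees of freedom before moderation, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Changes are ligated minus sham in log2, given with the standard error of the fit.

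Probes were named from the files (gene name, NCBI gene number, RefSeq accession or description) through a table of rabbit gene symbols of assembly mOryCun1.1, used for names only. Of 43603 probes 22639 had 1 symbol, covering 10035 symbols, 59 had several and 20905 had none. Probe positions are those of the files, on oryCun2. Where a gene had several tested probes, the 1 with the highest mean signal over all 6 arrays stands for it.

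There were 23 gene lists, all written before the data were examined, of which 6 were primary: contractile smooth muscle, fibrillar matrix, elastic fibre and basement membrane, matrix proteases and inhibitors, inflammatory cytokines and adhesion, and proliferation. The others were immediate early and dissociation stress, growth factors, excitation and relaxation, apoptosis, redox and nitric oxide, oxidative phosphorylation, ribosomal proteins, unfolded protein response, interferon response, and markers of endothelium, fibroblasts and meninges, monocytes and macrophages, lymphocytes, neutrophils, erythroid cells, neurons and glia. The redox list shares 1 gene with each of the endothelial, macrophage and neutrophil lists, and the protease list 1 with each of the macrophage and neutrophil lists. Lists were tested as sets with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists, and their members were also adjusted over the list alone.

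Named genes followed a rule fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among genes that passed, whose groups did not overlap and which were measured above background in both groups, read here as well above background on all 3 arrays of both. It also took up to 4 passing members of each list with the smallest p (where none passed, up to 2 given as values), a fixed set of smooth muscle, matrix, inflammatory and cell type genes, and up to 5 genes well above background on all 3 arrays of 1 group and on none of the other. For these last genes, and for listed genes read in 1 group only, a lower bound of the fold was computed by setting each array where the gene was not well above background to the lowest signal called well above background on that array, or to its own signal if that was higher.

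The alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, median centring, no filter on dim probes, a filter on all 6 arrays, the mean of all tested probes of a gene (for lists), the deposited value table, trend and robust variances, array weights, a replicate block, scan day as a block, an estimated correlation, and leaving out each array in turn. The alternatives added after the data were seen were normexp without spots whose background exceeded their signal, sham 2 and sham 3 averaged, and the mean of the lymphocyte or the macrophage markers as a covariate. The closeness of arrays was measured over genes with several probes as the covariance of the difference of a pair of arrays between separate probes of the gene. The model was tested on simulated data of the same size (27381 probes, 200 of them changed): it recovered 0% of changes of 1 log2 unit with 0 false calls, and 59.5% of changes of 2 log2 units with 7 false calls. The simulated noise was independent between probes and few probes changed. In the real data 2290 probes passed, 1960 of them at a change of at least 2-fold. The simulated shares and false calls therefore do not carry over to the comparison reported here. RNA integrity numbers were not used here, and 1 gene that the naming rule took is not reported here.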

Results

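Messenger RNA was measured in smooth muscle cells from the basilar artery of female New Zealand White rabbits with 6 one-colour rabbit oligonucleotide microarrays. Both common carotid arteries were tied in 3 rabbits, which raises flow through the basilar artery, and were only exposed in 3 sham rabbits. Cells were taken on day 5, and the labels give n = 3 rabbits per group. Each array read 43603 probes. On the sham arrays 58.7%, 61.3% and 63.4% of probes were well above background, and on the ligated arrays 61.9%, 63.7% and 61.6%. No spot of any array was saturated, and the median coefficient of variation between repeated spots ran from 4.76% to 5.57%. The number of arrays limits the precision of every value given here. All sham arrays were on slide 1 and all ligated arrays on slide 2, so slide and ligation cannot be told apart in any result. Of 10 spike-in controls, 6 read lower on every ligated than on every sham array, and 5 did so after scaling. The median difference over the controls was -0.81 in log2 after scaling, a difference that moves with slide and with ligation. It was not uniform over the ligated arrays. Before scaling, control E1A_r60_a135 had log2 signals of 9.01, 8.70 and 9.46 on the sham arrays. On the ligated arrays it had 7.27, 8.31 and 8.29. Controls E1A_r60_3 and E1A_r60_a104, also in that median, were dim, with log2 signals from 1.06 to 2.19. Sham 3 was scanned on scan day 2 and the other arrays on scan day 1.

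The comparison of ligated with sham arteries asks which genes differ in the smooth muscle cell preparation when flow through the vessel is raised. Transcripts of other cells were also read, such as the globin HBB2 at 7.74 ± 0.57 in sham (log2, SD, n = 3). The changes below therefore cannot be assigned to smooth muscle cells alone. TNFAIP6, which encodes a secreted hyaluronan-binding protein induced in inflammation, had the largest rise among named genes measured above background in both groups. Its normalised log2 signal was -1.97 ± 0.49 in sham and 3.56 ± 0.21 in ligated arteries (SD, n = 3), a 46.3-fold difference, and all 7 of its tested probes passed the test. EFNB1, a membrane-bound ephrin ligand, rose 36.0-fold on its 1 probe, from -2.38 ± 0.11 to 2.79 ± 0.99 (SD, n = 3). Over the alternative settings the lowest log2 change was 3.32 for TNFAIP6 and 2.90 for EFNB1. EFEMP1, a fibulin of the extracellular matrix, rose 15.5-fold, with a log2 change of 3.96 ± 0.20 (SE). The proteoglycan ESM1 rose by 3.92 ± 0.50 and the fatty acid carrier FABP5 by 3.68 ± 0.24. The adhesion protein SVEP1 rose by 4.09 ± 0.69, the mitochondrial import protein TOMM6 by 3.95 ± 0.66 and the endoplasmic reticulum retention receptor KDELR3 by 3.87 ± 0.57. The rest of the 12 largest rises, UBE2C, CDK1, NDC80 and MKI67, are genes of dividing cells. The calls of SVEP1, TOMM6 and KDELR3 ended without sham 2, without sham 3 and without ligated 2, and that of SVEP1 also without ligated 1. The highest adjusted p among these leave-outs was 0.0760 for SVEP1, 0.0747 for TOMM6 and 0.0634 for KDELR3. The TOMM6 probe was designed on an expressed-sequence clone. On oryCun2, the build the array files use, the TNFAIP6 probe lies on chromosome 7 from 90363252 to 90367714, the EFNB1 probe on chromosome X from 47437894 to 47437950, and the EFEMP1 probe on chromosome 2 from 130236082 to 130243561.

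Among the 12 largest falls, COX7A1 and COX6A2, the muscle forms of cytochrome c oxidase subunits, fell by 2.58 ± 0.20 and by 2.12 ± 0.20 on the log2 scale (SE). CKM, the muscle creatine kinase, had a log2 signal of 3.07 ± 0.50 in sham and 0.55 ± 0.15 in ligated arteries (SD, n = 3), a 5.74-fold fall. SLC2A4, the insulin-responsive glucose transporter, fell 4.33-fold from 4.71 ± 0.10 to 2.59 ± 0.17, and all 6 of its probes passed. CHCHD10, a protein of the mitochondrial intermembrane space, fell 4.08-fold from 6.56 ± 0.04 to 4.53 ± 0.05, and all 5 of its probes passed. RERGL, a Ras-like protein with high expression in contractile smooth muscle, fell 6.65-fold. The guanine nucleotide exchange factor RASGRP2 fell by 2.20 and the membrane protein SYPL2 by 2.37 on the log2 scale. AVP, which encodes the hormone vasopressin, fell 7.65-fold on its 1 probe, with a log2 change of -2.94 ± 0.53. That call ended in 5 of the 6 leave-outs, with a highest adjusted p of 0.0900, and held only without ligated 3, where the change was -3.55. The glycosyltransferase GCNT1 fell by 2.69, the potassium channel KCNA2 by 2.25 and the ubiquitin ligase PDZRN4 fell by 2.13. All 3 calls ended without sham 2 and without sham 3, that of GCNT1 also without ligated 1 and that of KCNA2 also without ligated 2. The highest adjusted p there was 0.0642 for GCNT1, 0.0976 for KCNA2 and 0.0538 for PDZRN4. The SLC2A4 probe lies on chromosome 19 from 11861805 to 11861864 and the AVP probe on chromosome 4 from 10059269 to 10059328, and the files give no position for the COX7A1, CKM and CHCHD10 probes.

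Of 27410 probes tested with limma, 2290 passed an adjusted p of 0.05, of which 1564 (68.3%) were higher and 726 lower in ligated arteries. At a change of at least 2-fold, 1960 passed, 1429 higher and 531 lower. On the probe that stands for each gene, 676 of 7573 named genes passed without that limit on fold, 473 higher and 203 lower. Of the 2290 probes, 792 had no gene symbol. Of 322 genes that passed with more than 1 tested probe, 318 had all tested probes in 1 direction. The groups did not overlap for 9523 probes, which is 34.7% of those tested. By chance 10% would do so if all arrays were independent of each other. Sham 2 and sham 3 were too close to count as independent, so 10% is too low a benchmark and overstates the excess. Sham 2 and sham 3 were far closer to each other than any other pair of arrays: the SD of the difference shared by separate probes of the same gene, over 981 genes, was 0.12 for them and at least 0.40 for every other pair. The labels give n = 3 rabbits per group but do not say whether an array of either group holds RNA of 1 rabbit or of a pool, and the n and SD of every value here rest on reading each array as 1 rabbit. With both averaged into 1 sample, an alternative chosen after that closeness was seen, 595 probes passed, and 592 of them were among the 2290. The count was 595 without sham 2, 1205 without ligated 1 and 752 without ligated 2. It was 552 without sham 3, which is also the value with scan day as a block. The lower probes shrank most: 80 were lower with both averaged, 80 without sham 2, 70 without sham 3 (87.3% higher), 284 without ligated 1 and 147 without ligated 2. With a normexp background correction (planned) limma called 0 probes, and 615 had an unadjusted p under 0.05, where 7498 did in the analysis reported. That correction was set by a few spots with very high local background, and it moved the median change of all tested probes from 0.01 to 0.21. With those spots left out, a choice made after seeing the data, 2223 probes passed, 1649 of them among the 2290, and 57.3% were higher. The calls of all 72 genes chosen by the naming rule that passed also ended under the planned normexp correction, and none of the 72 changed sign there. Among these 72 genes, every call that ended without sham 2 also ended with sham 2 and sham 3 averaged. The gene paragraphs do not repeat this for each gene.

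**Figure D1:**
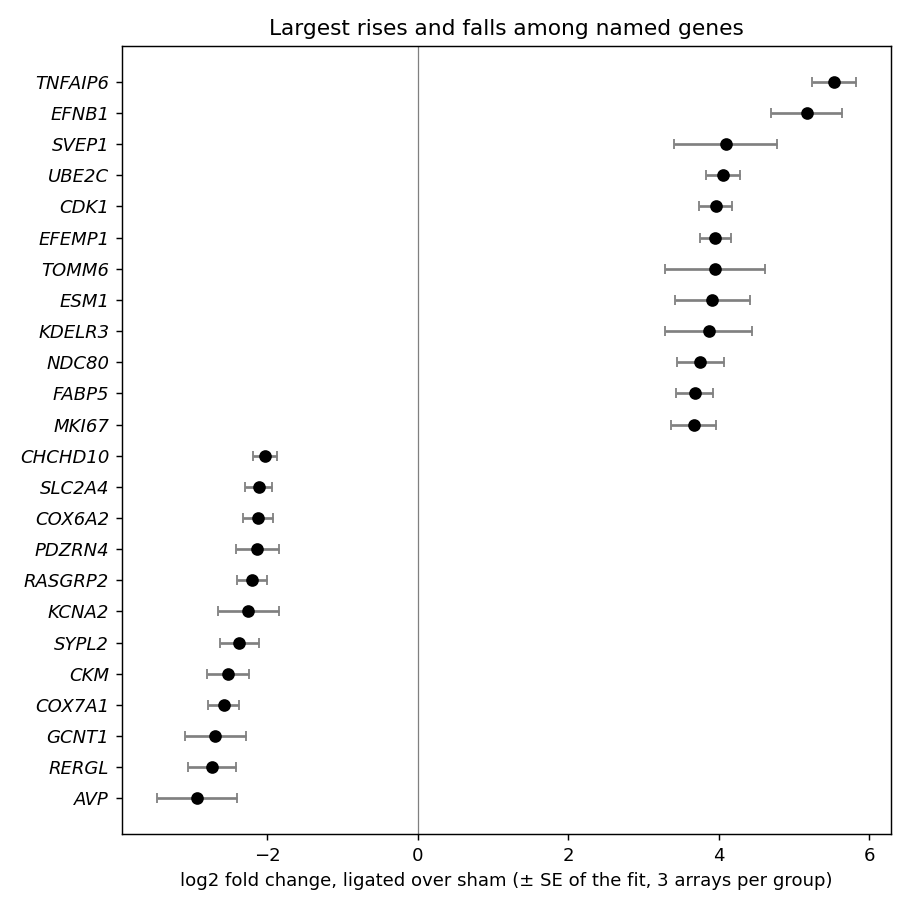
Log2 change between ligated and sham arteries (x axis) for the 12 largest rises and 12 largest falls of named genes (y axis), with bars for 1 SE (n = 3 per group). The largest rise is TNFAIP6 at 5.53 and the largest fall is AVP at -2.94.

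Most listed genes of dividing cells rose in ligated arteries, though the set test did not pass with an estimated correlation (adjusted p = 0.0938). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose 16.7-fold, from -2.65 ± 0.36 to 1.41 ± 0.07 (log2, SD, n = 3). CDK1, the kinase that drives entry into mitosis, rose 15.6-fold, from -2.66 ± 0.13 to 1.30 ± 0.31, and MKI67, the nuclear antigen of cycling cells, rose 12.7-fold, from -2.62 ± 0.44 to 1.04 ± 0.35. Over the alternative settings the lowest log2 change was 1.82 for UBE2C, 1.77 for CDK1 and 1.69 for MKI67, so the size of these folds depends on the processing. The spindle protein NUSAP1 rose by 3.09 ± 0.20 (SE) and the kinetochore protein NDC80 by 3.76 ± 0.31. The checkpoint kinase BUB1 also passed (adjusted p = 0.00311), and its size of change is uncertain, since it was well above background on 1 of 3 sham arrays. ANLN, a cytokinesis protein, was well above background on all 3 ligated arrays and not well above background on any sham array, which made it at least 16.3-fold higher. Without 1 array that bound ran from 12.5-fold (without ligated 2) to 25.0-fold (without ligated 3). PCNA, the clamp of DNA replication, had a log2 change of -0.04 (adjusted p = 0.925). Of 33 proliferation genes tested, 25 rose, 0 fell and 8 were not past the threshold, and 28 rose adjusted over the list alone. Their median log2 change was 2.35, or 2.11 with the 3 genes not well above background in sham put at their lower bound. The set test gave an adjusted p of 1.13e-20, and an adjusted p of 0.0938 with an estimated correlation. With scan day as a block 19 genes rose and the median was 2.29. Over probes above background on all 6 arrays, 16 of 23 tested genes rose, and with normexp without high-background spots 24 rose with a median of 1.01. The CDK1 probe lies on chromosome 18 from 25387842 to 25389573 and the MKI67 probe on chromosome 4 from 28803243 to 28803302.

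Genes for fibrillar collagens and their partners also rose. LUM, which encodes the collagen-binding proteoglycan lumican, rose from 3.49 ± 0.13 to 5.87 ± 0.09 (log2, SD, n = 3), a 5.21-fold rise seen on all 4 of its probes. COL1A1, a chain of the main collagen of fibrous tissue, rose 8.12-fold, from 3.13 ± 0.05 to 6.15 ± 0.50, on a probe designed on an expressed-sequence clone. COL6A1 rose 4.22-fold and COL5A1 3.71-fold. COL3A1, already abundant in sham at 8.16 ± 0.10, rose by 1.31 ± 0.19 (SE), a call that ended without sham 2, without sham 3 and with the replicate block (highest adjusted p without 1 array, 0.0686). COL5A3 and the plasma adhesion protein VTN were not well above background in sham arteries, and were at least 13.5-fold and at least 25.2-fold higher in ligated arteries. For VTN that bound was 45.0-fold without ligated 1 and 14.9-fold without ligated 3. For COL5A3 it ran from 10.8-fold without ligated 2 to 16.6-fold without ligated 3. SPP1, which encodes osteopontin, had a log2 change of 1.54 that was not past the threshold (adjusted p = 0.0789). DCN, a small proteoglycan like LUM, had a change of 0.36 (adjusted p = 0.325) on its brightest probe, or 0.23 without ligated 2, while 4 of its 6 probes passed with changes up to 1.04. Of 31 genes in the fibrillar matrix list, 21 rose, 0 fell and 10 were not past the threshold, with 26 higher adjusted over the list alone and a median log2 change of 1.64. The set test gave an adjusted p of 3.85e-15, and an adjusted p of 0.167 with an estimated correlation. The number that rose was 10 without sham 2, 9 without sham 3 (also with scan day as a block, median 1.68) and 11 without ligated 2, and it ran up to 27, with array weights, over the other settings. Markers of adventitial fibroblasts and meninges, which share 2 genes with this list, moved the same way, with a median of 0.85. The LUM probe lies on chromosome 4 from 70315640 to 70315699 and the COL1A1 probe on chromosome 19 from 37489117 to 37489176.

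Elastic fibre and basement membrane genes rose with them. FBN1, the main fibrillin of elastic microfibrils, rose 4.52-fold, from 3.20 ± 0.24 to 5.38 ± 0.26 (log2, SD, n = 3), on all 3 of its probes. FBN2 was at least 5.13-fold higher (4.54-fold without sham 3), being not well above background in sham arteries. COL4A2, a basement membrane collagen, rose by 1.16, but not without sham 2, without sham 3 or without ligated 2, nor with the replicate block (highest adjusted p without 1 array, 0.0786). With EFEMP1 among them, 13 of 17 genes rose, 0 fell and 4 were not past the threshold, and 14 rose adjusted over the list alone. The median log2 change was 1.57, the set test gave an adjusted p of 4.22e-09, and it gave an adjusted p of 0.167 with an estimated correlation. The number that rose was 3 without sham 2, 3 without sham 3 (also with scan day as a block, median 1.48), 7 without ligated 1 and 4 without ligated 2, and it ran up to 15, with array weights, over the other settings. No probe carried the symbol of elastin, ELN.

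Among matrix proteases and their inhibitors, TIMP1, an inhibitor of matrix metalloproteinases, rose 3.04-fold, from 5.77 ± 0.19 to 7.38 ± 0.27 (log2, SD, n = 3). MMP9, a gelatinase also made by neutrophils, rose by 3.22 ± 0.52 (SE), a size that is uncertain because MMP9 was well above background on 2 of 3 sham arrays. The gelatinase MMP2 rose by 1.29 and the inhibitor TIMP3 by 1.06. Of 21 genes, 6 rose, 0 fell and 15 were not past the threshold, while 6 rose and 1 fell adjusted over the list alone. The median log2 change was 0.52, with a set test adjusted p of 0.000872 and an adjusted p of 0.186 with an estimated correlation. All 4 calls ended without sham 2 and without sham 3, and those of MMP9, MMP2 and TIMP3 also without ligated 2. The highest adjusted p among leave-outs was 0.0613 for TIMP1, 0.0731 for MMP9, 0.0892 for MMP2 and 0.108 for TIMP3. The replicate block also ended the calls of MMP2 and TIMP3. In this list limma called 0 genes without sham 2, where 8 had an unadjusted p under 0.05, and 0 without sham 3 or with scan day as a block, where 7 did (median 0.44). It called 1 without ligated 2, 3 with the replicate block and 8 with the macrophage covariate. The TIMP1 probe lies on chromosome X from 32658284 to 32658343.

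Inflammatory cytokine genes rose in part. CXCL8, which encodes the neutrophil-attracting chemokine interleukin 8, rose 5.95-fold, from 3.64 ± 0.18 to 6.21 ± 0.48 (log2, SD, n = 3), on all 7 of its probes. LIF, a cytokine of the interleukin 6 family, rose 6.33-fold, from -2.85 ± 0.41 to -0.19 ± 0.10, and IL18 rose 3.61-fold on all 7 of its probes. IL6 rose by 1.73 ± 0.34 (SE), a call that ended without sham 2, sham 3, ligated 1 or ligated 2 and with the replicate block (highest adjusted p without 1 array, 0.118). The monocyte chemokine CCL2 had a log2 change of 2.23 ± 0.61 (adjusted p = 0.0744) and the adhesion molecule VCAM1 one of 0.76 (adjusted p = 0.190), both not past the threshold. The gene of inducible nitric oxide synthase, NOS2, had 7 probes and none was tested, since too few arrays read them above background. With TNFAIP6 among them, 8 of 26 genes in the list rose, 0 fell and 18 were not past the threshold, and 13 rose adjusted over the list alone. The median log2 change was 1.47, with a set test adjusted p of 1.22e-05 and an adjusted p of 0.282 with an estimated correlation. With the planned normexp correction the median was 0.74. The number that rose was 5 without sham 2, 4 without sham 3 (also with scan day as a block, median 1.72) and 4 without ligated 2, and it was 13 with the mean of all tested probes of a gene and up to 15, with array weights, over the other settings. In the same arrays the monocyte and macrophage markers had a median change of 0.21 and the neutrophil markers one of 0.34. The CXCL8 probe lies on chromosome 15 from 76369048 to 76369107.

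Contractile genes of smooth muscle lay lower in ligated arteries relative to the 75th percentile. On that scale the spike-in controls had a median difference of -0.81, which was not uniform over the ligated arrays. Their list mean, centred over the 6 arrays, was 0.70, 0.30 and 0.18 in sham and -0.18, -0.05 and -0.95 in ligated arteries. Markers of adventitial fibroblasts and meninges rose in the same arrays, with a median of 0.85. CSRP1, a LIM-domain protein of the actin cytoskeleton, fell 3.34-fold, from 5.79 ± 0.16 to 4.05 ± 0.08 (log2, SD, n = 3). SMTN, which encodes smoothelin, a marker of contractile smooth muscle, fell 3.41-fold, from 3.17 ± 0.29 to 1.40 ± 0.13. The integrin ITGA8 fell by 1.71 and the calcium-binding protein CASQ2 by 1.56 on the log2 scale, but neither call held without sham 2 or without sham 3 (highest adjusted p, 0.0619 and 0.0747). The 5th call was the intermediate filament gene DES at -1.11 ± 0.24 (SE; adjusted p = 0.0399), named after its values were seen, a call that among the leave-outs held only without ligated 2 (highest adjusted p, 0.156). Several abundant contractile genes were not past the threshold. The actin ACTA2 was at 8.11 ± 0.66 in sham and 7.16 ± 0.95 in ligated arteries, a change of -0.94 ± 0.54 (adjusted p = 0.310) that was -0.56 without sham 1 and -0.45 without ligated 3, and its probe may also read other actins, so its identity is uncertain. The myosin heavy chain MYH11 changed by -1.16 ± 0.40 (adjusted p = 0.125), TAGLN by -1.01 ± 0.36 (adjusted p = 0.133) and the transcriptional coactivator MYOCD by -0.69 (adjusted p = 0.525), which was 0.10 without ligated 3 and -1.25 without ligated 2. Of 32 genes, 5 fell, 0 rose and 27 were not past the threshold, with 9 lower adjusted over the list alone. The median log2 change was -0.90, with a set test adjusted p of 2.27e-07 and an adjusted p of 0.531 with an estimated correlation. The number that fell was 2 without sham 2 and 2 without sham 3 (also with scan day as a block, median -0.98), and it ran up to 14, with the lymphocyte covariate, over the other settings. As many as 2 genes rose there: 1 without ligated 3, 1 with array weights and 2 with the macrophage covariate. No probe carried the symbol of CNN1 or KLF4. The CSRP1 probe lies on chromosome 16 from 70047599 to 70047658 and the SMTN probe on chromosome 21 from 3561421 to 3561480.

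**Figure D2:**
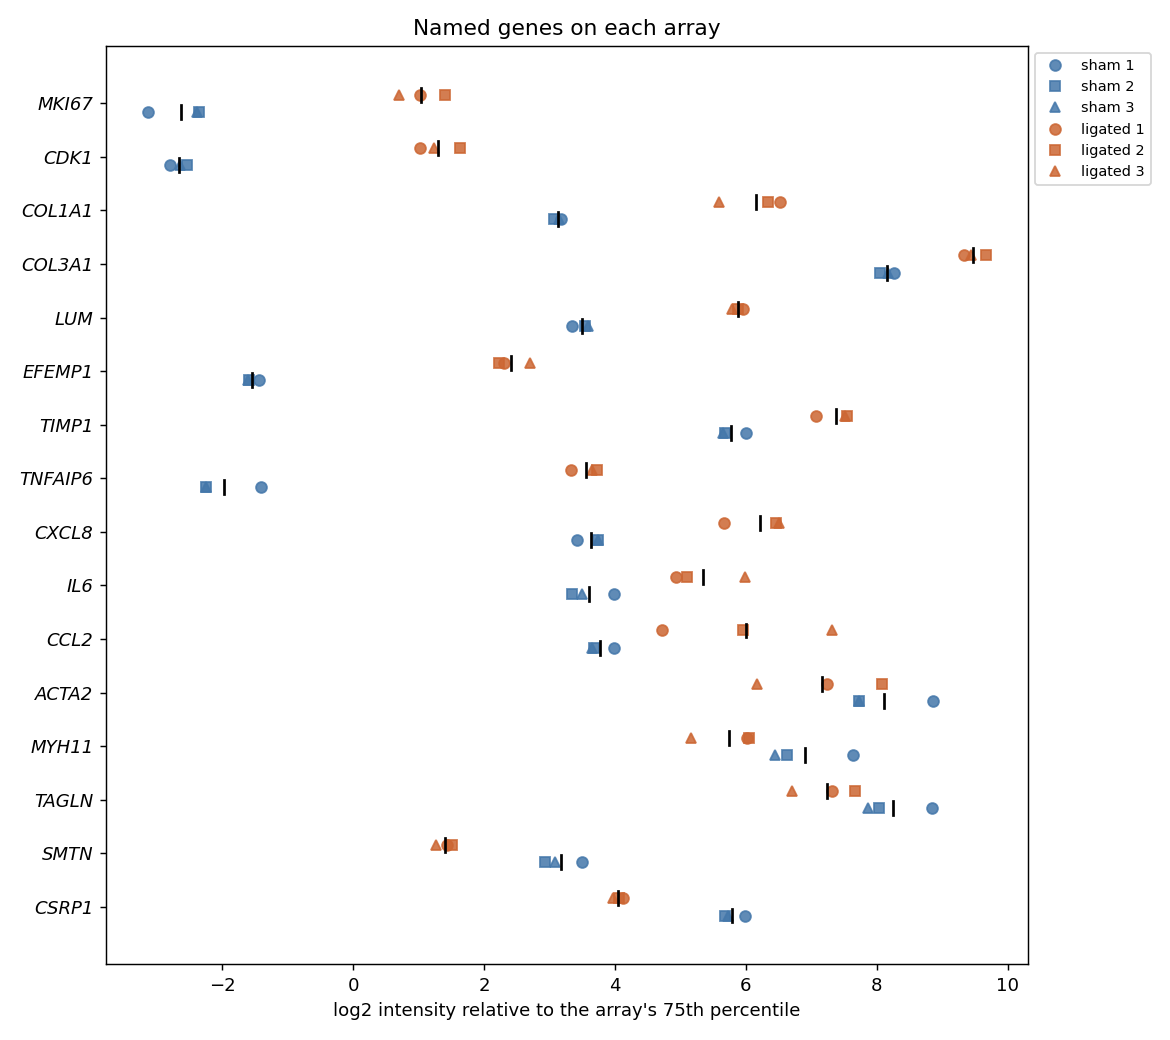
Log2 signal relative to the array's 75th percentile (x axis) of named genes (y axis) on each of the 3 sham arrays (blue points) and 3 ligated arrays (orange points), with a black bar at each group mean. CSRP1 has group means of 5.79 in sham and 4.05 in ligated arteries with no overlap, while the groups of ACTA2, with means of 8.11 and 7.16, overlap.

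Genes of excitation and relaxation fell in part. The voltage-gated potassium channel KCNA5 fell by 1.59 ± 0.20 (SE), the sarcoplasmic calcium release channel RYR2 by 1.70 and the cyclic GMP-dependent kinase PRKG1, which mediates relaxation by nitric oxide, by 1.41. RGS4, a brake on G protein signalling, rose by 2.18. Of the probes of these genes, 1 of 3 passed for RGS4 and 1 of 2 for PRKG1, with the other probes in the same direction. Of 39 genes, 7 fell, KCNA2 among them, 1 rose and 31 were not past the threshold, with 11 lower and 2 higher adjusted over the list alone. The median log2 change was -0.28 and the set test gave an adjusted p of 0.00210, with an adjusted p of 0.531 with an estimated correlation. On the same scale the spike-in controls had a median difference of -0.81, a larger fall, so the direction of this median depends on the scale used. The calls of RYR2, RGS4 and PRKG1 ended without sham 2 and without sham 3, and those of RYR2 and RGS4 also without ligated 2 (highest adjusted p 0.0640, 0.0642 and 0.0788 for RYR2, RGS4 and PRKG1). Without sham 2, without sham 3 and with scan day as a block 1 gene fell and 0 rose, where 14, 13 and 13 genes of the list had an unadjusted p under 0.05. Without ligated 2, 3 fell and 0 rose, and with array weights 11 fell and 2 rose.

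Several growth factor genes rose. IGF1, a growth factor for smooth muscle, rose 5.15-fold, from -1.21 ± 0.17 to 1.15 ± 0.16 (log2, SD, n = 3), on all 5 of its probes, and HGF rose 3.46-fold. The epidermal growth factor receptor ligand HBEGF rose by 1.56, a call that ended without sham 2 and without sham 3 (highest adjusted p, 0.0702). The receptor TGFBR2 rose by 2.19, a call that ended without sham 2, sham 3, ligated 1 or ligated 2 (highest adjusted p, 0.0693). The receptor PDGFRB had a log2 change of 2.78 ± 0.68 that was not past the threshold (adjusted p = 0.0572). Of 35 growth factor and receptor genes, 6 rose, 1 fell and 28 were not past the threshold. The gene that fell was FGF1 at -1.56 (adjusted p = 0.0190), named after its values were seen, a call that ended without sham 2, sham 3 or ligated 2 (highest adjusted p, 0.0871). Adjusted over the list alone, 9 rose and 3 fell. The median log2 change was 0.51 (0.34 without sham 3 and 0.32 without ligated 1 or ligated 2), with a set test adjusted p of 0.0427 and an adjusted p of 0.531 with an estimated correlation. The set call ended without sham 2 (0.0589), without sham 3 and with scan day as a block (0.0590), without ligated 1 (0.0991) and without ligated 2 (0.0813). It also ended with the planned normexp correction (0.212), with no filter on dim probes (0.0559), with the mean of all tested probes of a gene (0.134), with sham 2 and sham 3 averaged (0.0595) and with the lymphocyte covariate (0.0527). Without sham 2 and without sham 3, 2 genes rose, and without ligated 2, 4 rose, while 11 rose with the macrophage covariate.

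Most listed genes of mitochondrial respiration and of the ribosome read slightly lower in ligated arteries relative to the 75th percentile, though few passed singly. Both set calls ended with an estimated correlation. On the same scale the spike-in controls had a median difference of -0.81, a larger fall though not uniform over the ligated arrays, so the direction depends on the scale used. ATP5PO, a subunit of ATP synthase, fell by 0.94, with 4 of its 6 probes past the threshold and 1 probe at 0.52, and COX5B, a cytochrome c oxidase subunit, fell by 0.93. Both calls ended with quantile normalization, with the deposited value table, with no filter on dim probes and with the replicate block. That of ATP5PO also ended without sham 2, sham 3, ligated 1 or ligated 2, and that of COX5B without any 1 array (highest adjusted p, 0.159 and 0.156). Of 31 oxidative phosphorylation genes, 2 fell, 0 rose and 29 were not past the threshold, and 2 fell adjusted over the list alone, while 5 fell with array weights. The median was -0.45 (-0.30 without ligated 1), with a set test adjusted p of 2.04e-06 and an adjusted p of 0.531 with an estimated correlation. With quantile normalization the median was -0.17 and the adjusted p 0.0364, and limma called 0 genes where 5 had an unadjusted p under 0.05. Of 27 ribosomal protein genes limma called 0, also over the list alone, and 13 had an unadjusted p under 0.05. Called as lower were 6 with trend and robust variances, 5 with array weights and 5 with normexp without high-background spots. Of these genes 25 had a negative change, with RPS9 at -0.88 (adjusted p = 0.0626) on its brighter probe and at 0.27 on its other probe, and RPL14 at -0.70 (adjusted p = 0.0738). The ribosomal median was -0.48, with a set test adjusted p of 6.61e-05 and an adjusted p of 0.531 with an estimated correlation. Quantile normalization ended that set call, with a median of -0.25 and an adjusted p of 0.0952, and so did the deposited value table (0.106).

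Stress genes moved both ways or little. In the immediate early and dissociation stress list, IER3 rose by 1.35, the phosphatase DUSP1 rose by 3.03 ± 0.70 (SE) and the nuclear receptor NR4A2 fell by 1.29, with adjusted p of 0.0395, 0.0484 and 0.0431. Of its 21 genes 2 rose, 1 fell and 18 were not past the threshold, with 3 higher and 2 lower adjusted over the list alone. The median was 0.01, running from -0.16 to 0.37 without 1 array, with a set test adjusted p of 0.705 and an adjusted p of 0.890 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, rose by 0.87 and was the 1 apoptosis gene of 22 to pass. Adjusted over the list alone limma called 0 of these 22, where 3 had an unadjusted p under 0.05, and the median was 0.07, up to 0.16 without ligated 1 (set test adjusted p = 0.736, and adjusted p = 0.819 with an estimated correlation). NOX4, an oxidase that makes hydrogen peroxide, rose by 2.06 and was the 1 redox and nitric oxide gene of 26 to pass, also over the list alone. The redox median was -0.06, or -0.03 with genes at their bound, and ran from -0.18 to 0.02 without 1 array, and the set test adjusted p was 0.461, with an adjusted p of 0.700 with an estimated correlation. The chaperone HSPA5 rose by 0.95 and was the 1 unfolded protein response gene of 17 to pass, also over the list alone, with a list median of 0.29 (0.12 without sham 3 and 0.08 without ligated 1), a set test adjusted p of 0.461 and an adjusted p of 0.634 with an estimated correlation. None of the 6 calls of this paragraph held across the leave-outs: IER3 held only without sham 1, NR4A2 only without ligated 1, NOX4 and HSPA5 only without ligated 3, DUSP1 without ligated 1 or ligated 3, and CDKN1A in none. The replicate block ended all 6 calls, no filter on dim probes ended all but that of NOX4, and quantile normalization and the deposited value table ended those of NR4A2 and DUSP1. Among the leave-outs the highest adjusted p was 0.143 for IER3, 0.155 for NR4A2, 0.142 for DUSP1, 0.158 for CDKN1A, 0.0924 for NOX4 and 0.124 for HSPA5. Of 9 interferon response genes limma called 0, also over the list alone, where 3 had an unadjusted p under 0.05. IFIT3 was at 1.28 (adjusted p = 0.111), or 0.85 without ligated 2, and OASL at 1.69 (adjusted p = 0.136), the median was 0.23 (0.42 without ligated 1 and 0.03 without ligated 2), and the set test adjusted p was 0.369, with an adjusted p of 0.803 with an estimated correlation.

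Markers of other cell types were read in the same arrays. Of 14 adventitial fibroblast and meningeal markers 3 rose, LUM among them, and 4 rose adjusted over the list alone. The retinoic acid enzyme ALDH1A2 rose by 2.54, and the transporter SLC6A13 rose by 2.04, a call that among the leave-outs held only without sham 1 (highest adjusted p, 0.139), and that ended with no filter on dim probes. The fibroblast median was 0.85, with a set test adjusted p of 0.00248 and an adjusted p of 0.282 with an estimated correlation. The planned normexp correction ended that set call (0.0534), and with the mean of all tested probes of a gene 5 markers rose, and with array weights 7. Of 14 monocyte and macrophage markers the lectin LGALS3 rose by 1.28, a call that held without sham 1 or ligated 3 and in no other leave-out (highest adjusted p, 0.0843), and ended with the replicate block. CD68 was at 0.88 (adjusted p = 0.270), or 0.41 without sham 1, and 2 markers rose adjusted over the list alone. The macrophage median was 0.21, with a set test adjusted p of 0.132 and an adjusted p of 0.803 with an estimated correlation, and it ran from -0.15 without sham 1 to 0.49 without sham 3. The set call was made without sham 2 (0.0303), without sham 3 (0.0219) and without ligated 1 (0.0138), but not in the same fits with an estimated correlation (0.723, 0.706 and 0.648). It was also made with scan day as a block (0.0219), with sham 2 and sham 3 averaged (0.0272) and with the lymphocyte covariate (0.00211), where an estimated correlation gave 0.706, 0.707 and 0.256. Of 10 neutrophil markers MMP9 alone rose, also over the list alone, with a list median of 0.34, a set test adjusted p of 0.116 and an adjusted p of 0.634 with an estimated correlation. Without sham 2 and without ligated 2 the neutrophil median was 0.54 and 0.62 and the set passed (0.0319 and 0.0278), but not with an estimated correlation (0.625 and 0.540). Of 5 glia markers the gap junction gene GJA1 rose by 2.53 and the myelin gene PMP22 by 1.72, and 2 rose and 2 fell adjusted over the list alone. The glia median was -0.73, while the mean was 0.34 and the set test pointed up (adjusted p = 0.832, and adjusted p = 0.890 with an estimated correlation). That median was 0.45 without ligated 2, -0.45 without sham 2 and 0.41 over probes above background on all 6 arrays. No probe carried the symbol of MBP, and the 1 probe of GFAP was not tested.

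On the probe that stands for each gene, limma called 0 endothelial, lymphocyte, erythroid and neuron markers, also over each list alone, and 0, 1, 0 and 0 of them had an unadjusted p under 0.05. Of the 9 endothelial markers, ESAM was at -0.91 (adjusted p = 0.198), or -0.55 without sham 1, and MMRN2 at 0.68 (adjusted p = 0.202). PECAM1 was at 0.64 (adjusted p = 0.332), between 0.42 and 0.96 without 1 array, on a probe whose description names another gene. The endothelial median was 0.20, with a set test adjusted p of 0.832 and an adjusted p of 0.929 with an estimated correlation. It was 0.60 without sham 1, 0.58 without ligated 2, 0.02 without sham 2, and -0.03 without sham 3 or without ligated 3. Of the 13 lymphocyte markers, IL7R was at 2.24 (adjusted p = 0.147), or 1.30 without sham 1, and the pan-leukocyte gene PTPRC at -0.13 (adjusted p = 0.948), a value that turned positive with several settings. Both were well above background on 2 of 3 sham arrays. The lymphocyte median was -0.40, with a set test adjusted p of 0.842 and an adjusted p of 0.929 with an estimated correlation. It gave no firm direction, being -1.26 without sham 1, -1.10 without ligated 3, 0.18 without sham 2 and 0.06 without ligated 1. With the macrophage covariate the lymphocyte and erythroid sets passed (0.00325 and 0.0213), but not with an estimated correlation (0.491 and 0.558). Of the 4 erythroid genes, the globin HBB2 was at -1.88 (adjusted p = 0.339), between -3.33 and -1.12 without 1 array, and the haem enzyme ALAS2 had an adjusted p of 0.343 and was well above background on 1 of 3 ligated arrays, and the median was -1.81 (set test adjusted p = 0.150, and adjusted p = 0.700 with an estimated correlation). Without ligated 3 all 4 erythroid genes passed as lower, with a median of -3.34, which was -1.02 without ligated 1 and -1.08 without ligated 2. The erythroid set passed there (1.68e-05), with array weights (0.0238) and with the replicate block (0.0307), but not with an estimated correlation (0.223, 0.564 and 0.663). Of the 4 neuron genes, SYT1 was not well above background on any ligated array and was at least 1.75-fold lower there (1.3-fold without sham 1). That did not pass the threshold (adjusted p = 0.184), though 1 of its 3 probes did. UCHL1 was at 0.77 on its brightest probe, or 0.28 without ligated 2, while 2 of its 5 probes passed, with changes up to 1.87. With the mean of all tested probes of a gene, 1 neuron gene passed as lower. The neuron median was 0.24, between 0.08 and 0.46 without 1 array, the mean was -0.04 and the set test pointed up (adjusted p = 0.863, and adjusted p = 0.929 with an estimated correlation). ALAS2 and SYT1 had positive values under the planned normexp correction.

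**Figure D3:**
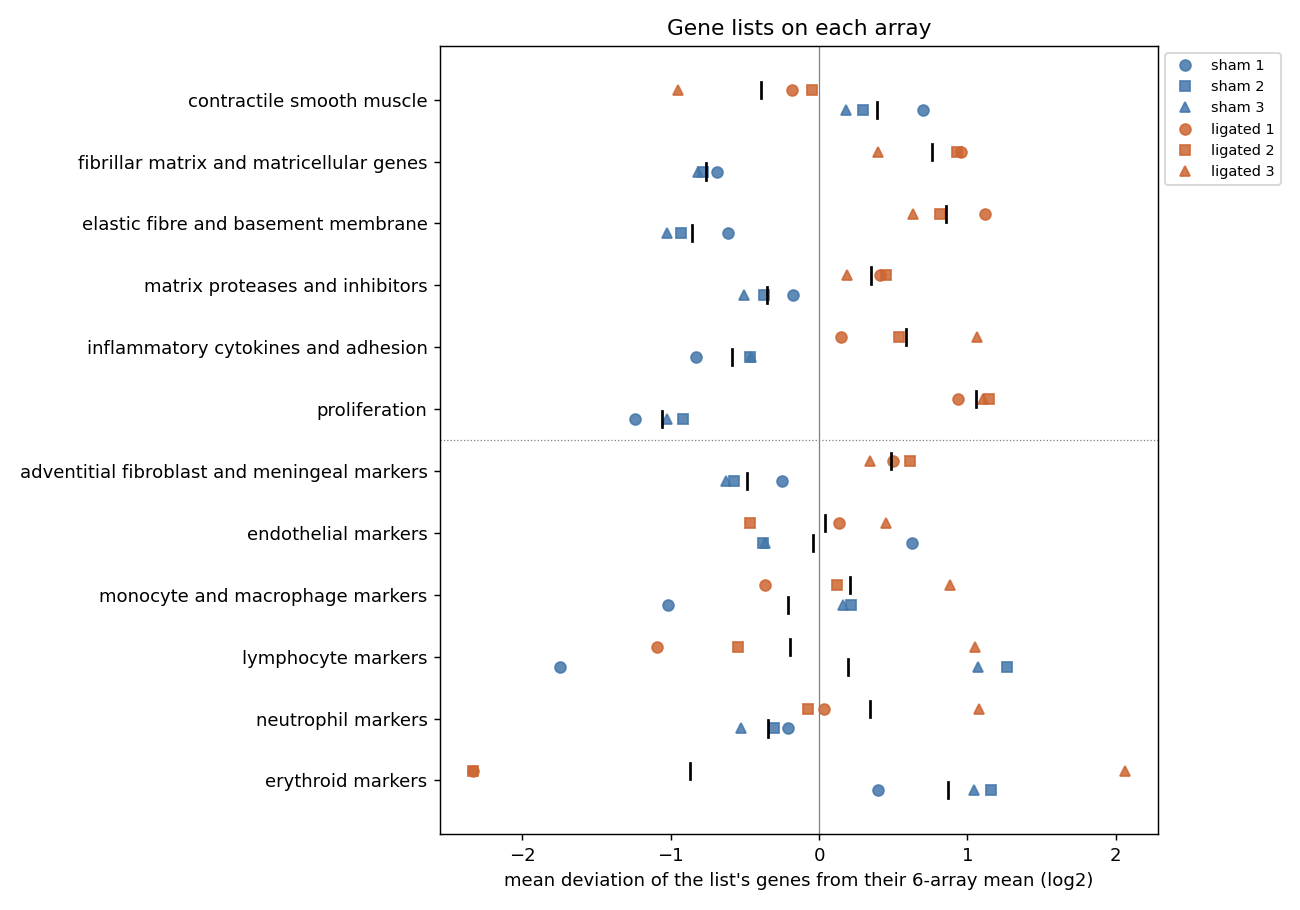
Mean deviation of a list's tested genes from their 6-array mean, in log2 (x axis), for gene lists (y axis) on each of the 3 sham arrays (blue points) and 3 ligated arrays (orange points), with a black bar at each group mean. Proliferation genes lie between -1.24 and -0.92 in sham and between 0.94 and 1.14 in ligated arteries, while lymphocyte markers run from -1.75 to 1.27 within sham.

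Beyond ANLN, VTN and COL5A3, other genes were read in 1 group only. In total 113 named genes were well above background on all 3 ligated and on no sham array, and 29 on all 3 sham and on no ligated array. The neuropeptide gene CCK was at least 6.79-fold and the autophagy gene EVA1A at least 6.31-fold higher in ligated arteries. Without 1 array these bounds fell as low as 5.86-fold for CCK (without sham 3) and 4.55-fold for EVA1A (without ligated 1). The call of CCK ended without sham 2 and without ligated 1, and that of EVA1A without sham 2, sham 3 or ligated 2 (highest adjusted p, 0.0687 and 0.0656). Both calls also ended with sham 2 and sham 3 averaged.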

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

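Averaging sham 2 with sham 3, the lymphocyte and macrophage covariates and normexp without high-background spots were chosen after seeing the data; the other settings were planned. All 6 primary lists kept their direction and their set call in every setting except with an estimated correlation, where medians of -0.90 (contractile), 1.64 (fibrillar matrix), 1.57 (elastic fibre), 0.52 (proteases), 1.47 (inflammatory) and 2.35 (proliferation) had adjusted p of 0.531, 0.167, 0.167, 0.186, 0.282 and 0.0938; the cause was not tested. Leaving out 1 array gave 552 to 2269 probes past the threshold, 482 to 1551 higher and 70 to 739 lower; fewer arrays were then fitted. Planned normexp gave 0 past, 0 higher and 0 lower, with 615 at an unadjusted p under 0.05. Sham 3, with a highest local background of 65253, then had a median of 10.4, where sham 1 had 6.57. With the 16 spots of sham 3 whose background exceeded their signal left out, its median was 6.55. Testing dim probes too gave 1524, with 326 lower, 78.6% higher and a median change of 0.17 over all probes. Trend and robust variances gave 1119 lower. Array weights gave 6098 (3349 higher, 2749 lower). The highest weights, 3.41 and 2.48, fell on sham 2 and sham 3, the closest pair. Sham 1 had 0.38 and the ligated arrays 0.56, 1.18 and 0.47, so counts with array weights lean on that pair. The replicate block gave 1295 (236 lower). Deviations from the group mean correlated at 0.432, -0.567 and 0.580 between same-numbered sham and ligated arrays. Sham 1 matched ligated 2 best, at 0.546, and the highest value was 0.655, for sham 2 with ligated 3. Such deviations sum to 0 within a group, and sham 2 and sham 3 were close. These values therefore cannot decide whether the numbers pair the rabbits. Scan day as a block gave 552 (482 higher, 70 lower), the same as without sham 3, the only array of its day. Averaging sham 2 and sham 3 gave 595 (515 higher, 80 lower). The lymphocyte covariate gave 4154 (2387 higher, 1767 lower) and the macrophage covariate 4881 (2790 higher, 2091 lower). For single genes, ALAS2 was 0.36 and SYT1 0.42 with normexp. PTPRC was 0.34 with normexp, 0.42 with sham 2 and sham 3 averaged, 0.29 with the lymphocyte covariate, and -1.21 to 0.48 without 1 array. MYOCD was -1.25 to 0.10 without 1 array. None of these 4 genes passed the threshold; the cause was not tested for them, nor for the counts with array weights, covariates or trend. Of 1619 pairs of a named gene and a setting, 1330 kept their call, 250 lost it, 30 gained it and 9 changed sign. Of 72 named genes that passed, 39 passed in all other settings run for them than planned normexp. Slide as a block could not be run, since each slide holds 1 group. Signal over background limits genes not well above background on any array of 1 group to lower bounds.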

Other observations

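The covariate tests, the count of slides, the use of the stress list, of marker pairs and of the fit without ligated 3 as tests, and the counts of splits were chosen after the results were seen, while that fit and the list medians themselves were planned. Several matrix genes outside the naming rule rose, and they were also picked after their values were seen. FN1, which encodes fibronectin, rose by 2.41 ± 0.24 (log2, SE, n = 3 per group; adjusted p = 0.00441), the proteoglycan VCAN by 3.15 (adjusted p = 0.0148), the matricellular POSTN by 1.95 (adjusted p = 0.0111) and the collagen cross-linking enzyme LOX by 1.82 (adjusted p = 0.0116). The call of FN1 held in every leave-out, that of POSTN ended without ligated 2 (0.0516), that of LOX without sham 2 (0.0525) and sham 3 (0.0588), and that of VCAN without sham 2 (0.0509), sham 3 (0.0552) and ligated 2 (0.0597). TNC was at 0.22 (adjusted p = 0.702), between 0.01 and 0.61 without 1 array, and THBS1 at 1.11 (adjusted p = 0.116), which passed without ligated 3 (0.0287). Of other hormone genes, OXT, which encodes the hypothalamic hormone oxytocin, was at 0.93 (adjusted p = 0.192), between 0.52 and 1.24 without 1 array, and POMC at -0.40, between -0.63 and -0.25.

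Arrays differed within the groups as well as between them. The 1st principal component held 63.7% of the variance and had scores of 47.8, -125 and -127 for the sham arrays and of 113, 101 and -10.7 for the ligated arrays. It did not separate the groups, since sham 1 scored above ligated 3. Over all probes, the log2 processed signal of sham 1 correlated at 0.9429 with sham 2 and 0.9440 with sham 3. Its correlations with ligated 1, ligated 2 and ligated 3 were higher, at 0.9565, 0.9653 and 0.9488. The B cell gene CD79B was at 1.32 on sham 2 and 1.30 on sham 3 but at -5.97 on sham 1, and at -5.94, -6.45 and -2.60 on the ligated arrays. The globin HBB2 was at 7.08, 8.10 and 8.05 on the sham arrays and at 4.32, 4.51 and 8.74 on the ligated arrays. Mean lymphocyte markers, centred over the 6 arrays, were at -1.75, 1.27 and 1.07 in sham and at -1.09, -0.55 and 1.05 in ligated arteries. Contractile genes were at 0.70, 0.30 and 0.18 in sham and at -0.18, -0.05 and -0.95 in ligated arteries.

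The list mean of proliferation genes was higher on every ligated than on every sham array. Lymphocytes that divide are a possible source. With the lymphocyte marker mean as a covariate the list's median stayed at 2.48 ± 0.27 (SE over members) and 26 genes passed. With the macrophage marker mean it stayed at 2.14 ± 0.26. Lymphocyte means were -1.75, 1.27 and 1.07 in sham and -1.09, -0.55 and 1.05 in ligated arteries. Macrophage means were -1.02, 0.22 and 0.16 in sham and -0.37, 0.12 and 0.88 in ligated arteries. Covariates that overlap so between the groups could hardly have removed the change, so these fits do not decide. The overlap itself argues against a larger number of either cell type as the whole cause, but not against more of them dividing. The slide stays open and cannot be told apart from ligation, since 0 slides hold both groups. Division of smooth muscle cells or fibroblasts under raised flow, which the arrays do not separate, may also be the source and was not tested.

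The inflammatory list was higher in ligated arteries by a median of 1.47. Macrophages could bring such transcripts. With the macrophage marker mean as a covariate the median stayed at 1.10 ± 0.48 (SE over members), with a set test adjusted p of 0.00141. With an estimated correlation the set test gave 0.364, where the list did not pass without the covariate either. That SE is taken over genes and does not measure the spread between arrays, so the fit does not decide on macrophages. A stronger response to the enzymes used to free the cells may add to the rise of the list. The immediate early and dissociation stress list had a median of 0.0094 with an SD of 0.96 over members that went both ways, so it decides nothing. Slide and a response of the vessel wall to flow also stay open, as untested.

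The contractile list was lower in ligated arteries by a median of -0.90. Ligated 3 had its lowest values, but without that array the median was -0.66 ± 0.19 (SE over members), which argues against ligated 3 alone as the source of the lower median. That SE is taken over genes and does not measure the spread between arrays. A lower share of smooth muscle cells could lower the list. It would raise the markers of the other cell types alike only if these kept their proportions to each other. Of 10 pairs of such marker lists, endothelial against fibroblast markers differed most for its error, at -0.89 ± 0.41 (SE between arrays). A gain of 1 cell type alone would also give unequal lists, so this test could not exclude a lower share. A lower share and a change within smooth muscle cells cannot be told apart. Slide stays open here too.

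The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2290 probes and was 1 of 10 with a count as large, with 614 as the highest other count (sham 1, ligated 1 and ligated 2 against the rest). Splits that put the close pair sham 2 and sham 3 on opposite sides all gave 0, while the 614 came from a split that keeps that pair together. The share of 1 in 10 therefore overstates the evidence. For absolute list medians, 1 of the 10 splits was as large for contractile genes (0.90, highest other 0.65), fibrillar matrix (1.64, 0.71), elastic fibre (1.57, 0.87), inflammatory (1.47, 0.82) and proliferation genes (2.35, 0.89). For proteases 2 of the 10 were (0.52, highest other 0.59).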
